A study of Mus musculus with 12 samples.

How the data were processed

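RNA of laser-captured Leydig cells from single mice was amplified for 2 rounds, labelled with Cy3 or Cy5 and hybridised in pairs to a whole-genome Agilent mouse array, per the labels' protocols. The labels speak of 4 mice per group in the exposure; arrays of 2 DEHP and 3 vehicle mice are used here, and the others are not analysed here. The mice were 21 weeks old. The 12 arrays lie on 3 slides of 4 arrays: slide 1 holds the arrays of vehicle mice 1 and 2 with DEHP RNA in Cy5, slide 2 the same pairs with vehicle RNA in Cy5, and slide 3 all arrays of vehicle mouse 4 in both orientations.

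The deposited scanner files give spot intensity (mean signal and median local background in each channel) from Feature Extraction 9.5.1.1, per the file headers, with no normalization between arrays. They also give the software's processed intensity, background-subtracted and dye-normalized, and a log10 ratio of red over green, per the file headers; the latter was used only to check directions. Flags of 0 or 1 per spot, deposited with the signals, mark spots well above background, saturated or outlying. The deposited value table of the series holds the authors' log2 ratios for 13669 probe spots. Its scale and direction are not stated in the sources used here: set against the scanner's log ratios after turning both the same way, its columns correlated at r = 0.915 to 0.993 with slopes of 0.842 to 0.932, ran as DEHP over vehicle, and had medians from -0.06 to 0.00. Its filter and its exact normalization stay unknown. The submitters' processing notes name limma, with no version.

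Everything else was computed here in R 4.3.3 with limma 3.58.1. Background was corrected with normexp (offset 50), each array was normalized with loess with control spots at weight 0, and control spots and outlier-marked spots (0.332% to 0.604% of probe spots per array) were then left out. Spots of the same probe were averaged. For each probe, least squares on the 12 log ratios gave a value for each of the 5 mice, relative to their mean, and a dye effect. A probe was kept where it was well above background on at least 50% of the arrays of at least 2 mice (21198 of 41174 probes), and each gene was represented by its probe of highest mean intensity. The mouse is the replicate: the repeated arrays of a mouse add precision to its value and not to the number of animals. The array number limits the precision of each value, and the 5 mice limit that of the group comparison.

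Of the 15830 tested genes, 10550 were named through their RefSeq accession, 1894 by a current symbol and 971 by an older symbol with a unique current equivalent, and 2415 keep the name in the file. The step for older symbols was added after a first look at the results. It changed names, and with them which probe stands for a gene, but no probe's value. Probe positions are those of the files, on mouse assembly mm7.

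DEHP and vehicle mice were compared with lmFit and eBayes on the 5 mouse values (3 residual degrees of freedom before moderation), with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p values in the text are limma's. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over 29 lists, with an estimated correlation and fry beside it. No list passed with an estimated correlation, and none with fry (adjusted p 0.972 for each), which tests only whether the genes of a list move one way. With an estimated correlation camera also uses only the residual degrees of freedom, so a list can hardly pass with so few mice. Sertoli cell markers had an estimated correlation of -0.03, below the preset 0.01, yet their unadjusted camera p went from 0.00137 to 0.0377. A call lost there thus does not show that correlation within the list produced it. Differences between single mice were tested on the 12 array log ratios and compare extracts only. The functions were tested on simulated arrays with 200 changed genes. With no change simulated, the fit on 5 mice called 0 genes and had 5.06% at an unadjusted p under 0.05. The simulated genes varied independently of one another, unlike those of the real mice.

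The lists, the design, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, among genes with a symbol, the 12 largest rises and the 12 largest falls past the threshold with no overlap of mice, filled up by lowest p where fewer passed; fixed steroidogenic, Leydig cell, PPAR alpha and cholesterol genes; and from each list the members past the threshold, up to 4, or else the 2 of lowest p. Some genes that the rule takes are not reported here. Alternatives covered background, normalization, the filter, probes per gene, the unit of replication, dye and slide, left-out mice and the authors' value table.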

Results

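Gene expression was measured in Leydig cells, the testosterone-producing cells of the testis interstitium, cut from frozen testis sections by laser capture. The adult male C57BL/6J mice had received di-(2-ethylhexyl) phthalate (DEHP), a plasticiser, at 200 mg per kg per day in corn oil for 21 days by gavage, or corn oil alone (vehicle). Two-colour Agilent arrays compared 2 DEHP mice, numbered 1 and 4 in the labels, with 3 vehicle mice, numbered 1, 2 and 4. Each DEHP mouse was hybridised against each vehicle mouse in both dye orientations, which gave 12 arrays, 6 with DEHP RNA in Cy5 and 6 with DEHP RNA in Cy3. The 12 arrays hold 5 animals, so 5 is the number of replicates in every comparison of the groups.

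Between 45.4% and 54.4% of the probe spots in the red channel, and between 35.5% and 46.1% in the green channel, were well above background. The log ratios of the 2 arrays of a pair of mice, turned the same way, correlated across genes with r between 0.61 and 0.95. Among the spiked-in control RNAs, the scanner software's observed log ratios ran at 0.775 to 0.895 of the expected ones, so that fold changes in its own log ratios were somewhat compressed. The values tested here were normalized otherwise and left the control spots out, so their compression was not measured. After filtering, 15830 genes were tested. Values are log2 levels of each mouse relative to the mean of the 5 mice, given as mean ± SD, with n = 2 for DEHP and n = 3 for vehicle.

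The first comparison asked which genes differed in the captured Leydig cell material after DEHP. The clearest separation of single genes lay in transcripts with both DEHP mice above all 3 vehicle mice or below them, none of which passed the test across all genes. Lpar4, a receptor for lysophosphatidic acid (probe at mm7 chromosome X, 102259549 to 102259608), was at 0.74 ± 0.25 in DEHP mice and -0.50 ± 0.24 in vehicle mice, a log2 difference of 1.24 (SE 0.24). The vehicle level was well above background on a share of 0.75 of the arrays, and over the alternatives the difference ran from 1.06 to 2.52. Mindy3, a deubiquitinase (chromosome 2, 12286926 to 12286985), was at -0.48 ± 0.04 in DEHP mice and 0.32 ± 0.17 in vehicle mice, a difference of -0.81 (SE 0.20). Prm1, the protamine that packs sperm DNA (chromosome 16, 10473905 to 10473964), was at 0.60 ± 0.39 against -0.40 ± 0.31. Its probe was well above background on all arrays of both groups, at a mean log2 intensity of 17.4 in DEHP and 16.4 in vehicle mice. The probe of the Leydig cell hormone gene Insl3 lay at 16.1 and 16.4. The captured material thus held spermatid RNA in both groups.

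No gene passed an adjusted p of 0.05 in limma with 5 mice, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 136 genes, 80 higher and 56 lower after DEHP, or 0.859% of the genes tested. The groups did not overlap for 1452 genes (9.17%), where chance gives 20% for 2 against 3 mice. The genes of lowest p with a symbol, none past the threshold, included on the higher side Lpar4, Eif3a, Hspa1l, Slc26a3, Wac, Ywhab, Asb4, Rb1cc1, Cngb3, Prm1 and Minar2. Their log2 differences ran from 0.65 for Cngb3 to 1.33 for Slc26a3, an anion exchanger, but the vehicle level of these 2 genes lay near background (well above it on a share of 0.5 and 0.67 of the arrays). Over the alternatives they ran from 0.60 to 2.62 and from 0.93 to 2.88. On the lower side they included Scube1, Mindy3, Nxf3, Senp8, Gtf2h4, Igfbp1, Ahsg, Pcgf6, Plagl1, Hpdl and Tada1, from -0.57 for Tada1 to -1.28 for Ahsg, a fetuin. The DEHP level lay near background for Scube1 and Igfbp1, well above it on a share of only 0.417 and 0.0833 of the arrays. A second probe for Ywhab lay at -0.08 against 0.71 for the probe used, the probes of Wac ran from -0.01 to 1.03 and those of Rb1cc1 from 0.15 to 0.99, and a second probe for Eif3a lay at 0.12 against 0.82. In simulated arrays with the spreads of these mice, the same fit recovered 4% of genes changed by 1 on the log2 scale, 56% of those changed by 1.5, 86% of those changed by 2 and 96% of those changed by 3. Treating the 12 arrays as independent gave 2123 genes in limma, 1111 higher and 1012 lower, but with no gene changed in the simulation that fit called 5433 of 15803 genes. Each simulated gene varied on its own, whereas 1 component shared across genes held 68.8% of the variance of the real mice. With no change simulated, 5.06% of genes had an unadjusted p under 0.05 in the fit on 5 mice, against 0.859% in the real data. The simulated rates therefore need not hold for these mice.

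Steroidogenic genes did not separate the groups. Of 30 measured genes of the steroidogenesis list, 9 lay above 0 and 21 below in the DEHP minus vehicle difference, none passed over all genes or adjusted over the list alone, and the median difference was -0.11. Star, which carries cholesterol into the mitochondrion, was at 0.05 ± 1.09 in DEHP mice and -0.03 ± 0.81 in vehicle mice (chromosome 8, 24570752 to 24570811). Its difference of 0.08 had a 95% interval of -1.48 to 1.63. Cyp11a1, the side-chain cleavage enzyme, differed by -0.38 (SE 0.59), Hsd3b1 by -0.59 (SE 0.85), its relative Hsd3b6 by -0.02 (SE 0.35) and Cyp17a1 by -0.20 (SE 0.53). Hsd17b3, which makes testosterone, differed by 0.57 (SE 0.38). The steroidogenesis list had a camera adjusted p of 0.725. The direction depended on the mice used: the median was 0.30 without DEHP mouse 4 (adjusted p = 0.000199), -0.55 without DEHP mouse 1 (0.00386) and -0.31 without vehicle mouse 1 (0.0300). With an estimated correlation the adjusted p values were 0.839, 0.710 and 0.708. The fits without a DEHP mouse hold 1 DEHP mouse, which is assumed to vary like the vehicle mice, and all their spread comes from these.

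The wide errors of these genes came from differences between mice of the same group. Star was at 0.81 in DEHP mouse 1 and -0.72 in DEHP mouse 4, and at -0.95 in vehicle mouse 1 against 0.57 and 0.29 in vehicle mice 2 and 4. Insl3, a Leydig cell hormone, was also lowest in DEHP mouse 4 and vehicle mouse 1, at 0.91 and -1.29 in DEHP mice 1 and 4 and at -1.02, 0.50 and 0.90 in vehicle mice 1, 2 and 4, a group difference of -0.32 (SE 0.83). Of the other Leydig cell genes, the luteinizing hormone receptor Lhcgr differed between the groups by -0.25 (SE 0.31) and Scarb1 by -0.17 (SE 0.54). Lhcgr, Nr5a1 and Tspo were well above background on a share of only 0.58, 0.25 and 0.33 of the arrays in DEHP mice and 0.83, 0.5 and 0.75 in vehicle mice, so no difference is given for Nr5a1 and Tspo. The Leydig cell identity list, with 3 of 22 measured genes above 0 and 19 below, had a median difference of -0.24 and a camera adjusted p of 0.0770. Its adjusted p was 0.968 with an estimated correlation, and 0.0278 with camera on ranks, which also takes the preset correlation. The median was -0.59 without DEHP mouse 1, 0.24 without DEHP mouse 4, -0.56 without vehicle mouse 1, -0.16 without vehicle mouse 2 and -0.05 without vehicle mouse 4, with adjusted p values from 0.000226 to 0.871. With an estimated correlation none of these fits called a list.

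**Figure D1:**
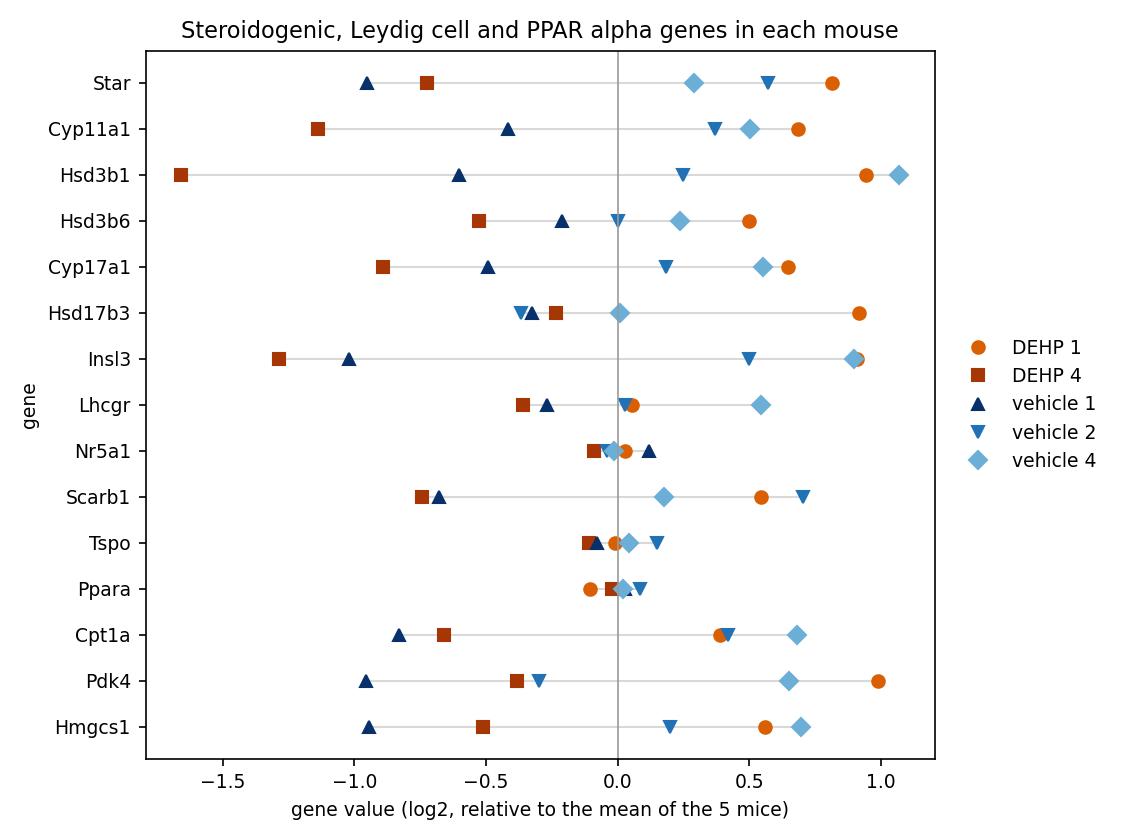
Level of 15 steroidogenic, Leydig cell, PPAR alpha and cholesterol genes fixed before the data were examined, on the x axis as log2 relative to the mean of the 5 mice, with 1 point per mouse and a grey line over their range. For Star, DEHP mouse 4 at -0.72 and vehicle mouse 1 at -0.95 lie on the left, and the other 3 mice between 0.29 and 0.81.

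DEHP is a peroxisome proliferator, and targets of the receptor PPAR alpha were examined next. The list held fatty acid oxidation genes and other genes that PPAR alpha ligands induce in liver, so it need not cover targets in Leydig cells. Of 40 measured targets, 13 lay above 0 and 27 below, with a median of -0.12, none past the threshold over all genes or adjusted over the list alone, and a camera adjusted p of 0.650. Cpt1a, which admits fatty acids to the mitochondrion, differed by -0.23 (SE 0.55), and Pdk4, a kinase that restrains pyruvate oxidation, by 0.51 (SE 0.60). The receptor gene Ppara differed by -0.11 (SE 0.18). No probe of Cyp4a10 or Cyp4a14 passed the filter for signal above background. The members of lowest p were Cpt1b, at a difference of 0.76 (SE 0.31), and Hsd17b4, at -0.46 (SE 0.30). The list's median was 0.27 without DEHP mouse 4 and -0.51 without DEHP mouse 1, each a fit of 1 DEHP mouse with spread from the vehicle mice alone. Their adjusted p values were 0.00123 and 0.00621, and 0.839 and 0.710 with an estimated correlation.

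Cholesterol synthesis genes gave 10 members above 0 and 15 below out of 25 measured, with a camera adjusted p of 0.835. Their median of -0.16 was 0.21 without DEHP mouse 4 and -0.55 without DEHP mouse 1, each a fit of 1 DEHP mouse. It was -0.39 without vehicle mouse 1 (camera adjusted p = 0.0239, and 0.708 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, differed by 0.04 (SE 0.57). Lipogenesis (26 genes), xenobiotic metabolism (27 genes) and oxidative stress (30 genes) had camera adjusted p values of 0.616, 0.835 and 0.616. The medians of these lists were 0.07, 0.33 and 0.33 without DEHP mouse 4 and -0.22, -0.48 and -0.27 without DEHP mouse 1. Among their members, Fasn differed by -0.69 (SE 0.59), the xenobiotic receptor Nr1i3 by 0.58 (SE 0.29) and Keap1, which holds the oxidative stress regulator Nrf2 in check, by 0.85 (SE 0.29).

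Spermatid markers were the 1 list of 29 that rose after DEHP as a set. Of 35 measured members, 33 lay above 0 and 2 below, with a median log2 difference of 0.35 and a camera adjusted p of 8.80e-10. The correlation estimated among its members was 0.71, against the preset 0.01, and the camera adjusted p with it was 0.968. No member passed the test on its own or adjusted over the list alone. Tnp1, a transition protein of condensing sperm chromatin, was at 0.69 ± 0.81 in DEHP mice and -0.46 ± 0.26 in vehicle mice. The median of the list was -0.04 and 0.62 in DEHP mice 1 and 4 and 0.26, -0.45 and -0.36 in vehicle mice 1, 2 and 4, so vehicle mouse 1 lay above DEHP mouse 1. The median difference was 0.77 without DEHP mouse 1, 0.65, 0.21 and 0.32 without vehicle mice 1, 2 and 4, and 0.05 without DEHP mouse 4, where the adjusted p was 0.301. It was 0.38 and 0.21 on slides 1 and 2 alone, which hold the same 4 mice in opposite dye orientations. Each of these 2 differences therefore also holds the dye effect. On slide 3, which holds vehicle mouse 4 alone with the same DEHP mice, the median difference was 0.58. Slide 3 thus has another vehicle animal, but no slide repeats the comparison with new DEHP animals. With a dye effect per slide it was 0.35.

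Spermatocyte markers had 15 members above 0 and 15 below (median 0.00, camera adjusted p = 0.918), but this balance depended on the mice used. The median was 0.31 without DEHP mouse 1 (adjusted p = 0.0104) and -0.21 without DEHP mouse 4 (4.83e-05), each a fit of 1 DEHP mouse. With an estimated correlation the adjusted p values were 0.710 and 0.839. Spermatogonial markers gave 11 above and 5 below (camera adjusted p = 0.667). Their median of 0.09 was 0.24 without DEHP mouse 1 (adjusted p = 0.216) and -0.23 without DEHP mouse 4 (0.000233, and 0.839 with an estimated correlation). In that list the RNA-binding protein gene Dazl differed by -0.47 (SE 0.22), with a second probe at -0.03.

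**Figure D2:**
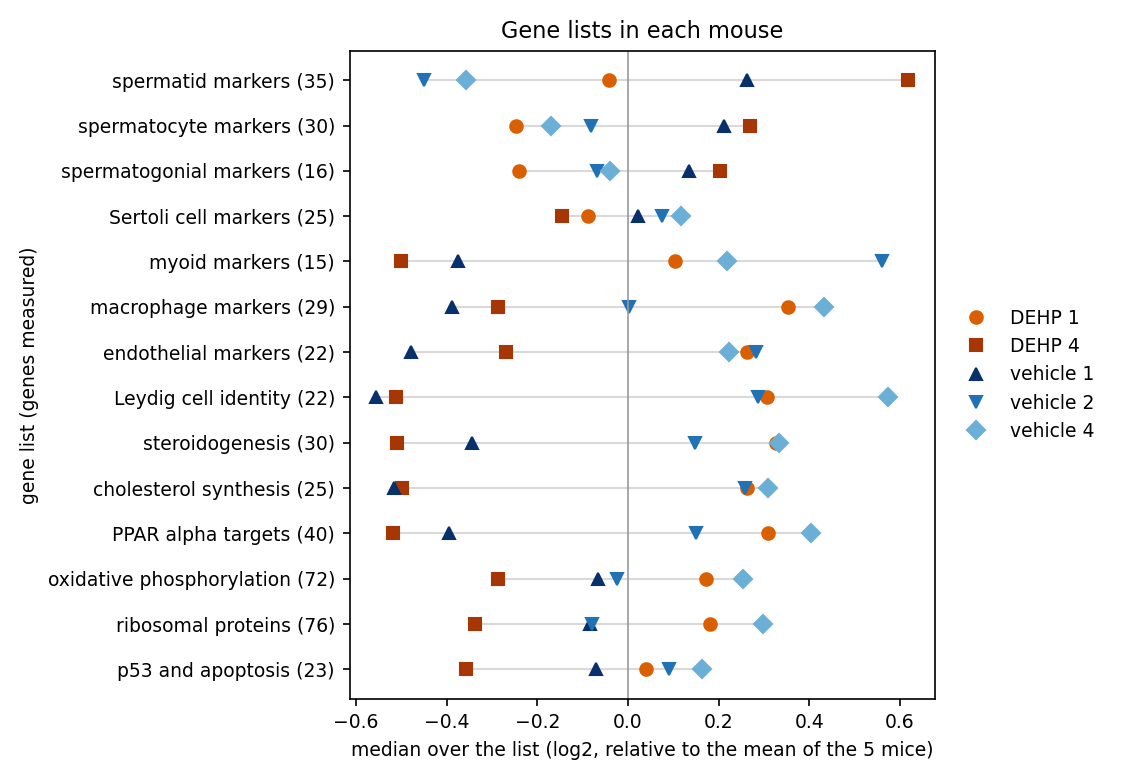
Median level of 14 gene lists in each mouse, on the x axis as log2 relative to the mean of the 5 mice, with 1 point per mouse, a grey line over their range and the number of genes measured in brackets. The steroidogenesis list lies at -0.51 in DEHP mouse 4 and -0.34 in vehicle mouse 1, and at 0.33, 0.15 and 0.33 in DEHP mouse 1 and vehicle mice 2 and 4.

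Further lists fell as sets after DEHP with the preset correlation. Each of these calls was lost with an estimated correlation, but all 29 lists had a camera adjusted p of 0.968 there. With 3 residual degrees of freedom that variant left little room for any call. The p53 and apoptosis list had 19 of 23 members below 0, with a median of -0.14 and an adjusted p of 0.0132. Its members of lowest p were Perp, a p53 target of cell adhesion, at -0.91 (SE 0.33), and the pro-apoptotic Bbc3 at -0.56 (SE 0.23). Sertoli cell markers had 17 of 25 below 0, with a median of -0.19 and Cst9 at -0.66 (SE 0.26). Myoid markers had 14 of 15 below 0, with a median of -0.28 and Cnn1, a smooth muscle calponin, at -0.86 (SE 0.41). Oxidative phosphorylation had 55 of 72 below 0 and a median of -0.12, and ribosomal proteins 53 of 76 and a median of -0.17. These 4 lists also had an adjusted p of 0.0132. Each of the 5 calls was also lost when 1 mouse was left out. The p53 median was 0.03 without DEHP mouse 4 (adjusted p = 0.599) and -0.07 without vehicle mouse 4 (0.0779), and the Sertoli median -0.17 without DEHP mouse 1 (0.118) and -0.05 without vehicle mouse 4 (0.0805). Without DEHP mouse 4, a fit of 1 DEHP mouse with spread from the vehicle mice alone, the medians of the oxidative phosphorylation, ribosomal protein and myoid lists were 0.11, 0.13 and 0.08. Without DEHP mouse 1 they were -0.30, -0.39 and -0.55, and without vehicle mouse 4 they were -0.03, -0.02 and -0.22 (adjusted p = 0.895, 0.944 and 0.0646). No fit without a mouse called a list with an estimated correlation, with smallest adjusted p values of 0.708 to 0.991.

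The other lists did not pass in camera with the preset correlation. Endoplasmic reticulum stress had 13 of 22 members above 0 (adjusted p = 0.534), with the chaperone gene Hspa5 at 0.85 (SE 0.34) and Calr at -0.60 (SE 0.27), with a second Calr probe at 0.46. Immediate early genes had 15 of 23 below 0 (0.0770), inflammation 12 of 15 (0.443), matrix 15 of 23 (0.426) and stromal markers 12 of 16 (0.668). Without vehicle mouse 1 these lists had medians of -0.19, -0.32, -0.41 and -0.37 with camera adjusted p values of 0.01835, 0.00840, 0.00111 and 0.0166, each 0.708 with an estimated correlation. Macrophage markers had 18 of 29 below 0 (0.918), endothelial markers 16 of 22 (0.835) and blood markers 2 of 3 (0.736). The macrophage median was 0.35 without DEHP mouse 4 and -0.27 without DEHP mouse 1. It was -0.23 without vehicle mouse 1 (camera adjusted p = 0.0369) and 0.13 without vehicle mouse 4 (0.0261). The endothelial median was 0.20 without DEHP mouse 4, -0.32 without DEHP mouse 1 and -0.41 without vehicle mouse 1 (0.00366). The cyclin gene Ccna2 differed by -0.46 (SE 0.21), the proteasome activator gene Psme3 by 0.42 (SE 0.19) and the vascular receptor gene Kdr by 0.37 (SE 0.23). The nuclear receptor gene Nr5a2 lay near background in vehicle mice, and its difference ran from 0.16 to 1.57 over the alternatives. Interferon, heat shock, circadian, cell cycle, nuclear receptor and proteasome lists had adjusted p values of 0.918, 0.918, 0.918, 0.927, 0.918 and 0.821. In the spermatogonial, heat shock, circadian, interferon, nuclear receptor and cell cycle lists, the median, the mean and the direction of the test differed in sign.

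The design also allowed mice of the same group to be compared through the repeated arrays, a comparison of extracts and not of conditions. DEHP mice 4 and 1 differed in limma for 12253 of 15830 genes (77.4%), 5748 higher and 6505 lower in mouse 4. Vehicle mouse 1 differed from the mean of vehicle mice 2 and 4 for 11415 genes, 5364 higher and 6051 lower. Between DEHP mice 4 and 1, 32 of 35 spermatid markers were higher in mouse 4 and 1 was lower, while 23 of 30 steroidogenesis genes and 16 of 22 Leydig cell identity genes were lower. Between vehicle mouse 1 and vehicle mice 2 and 4, 31 spermatid markers were higher, and 23 steroidogenesis and 18 Leydig cell identity genes were lower. Across genes, which are not independent replicates, the 2 differences correlated with r = 0.73. Of 9698 genes called in both, 8435 (87.0%) ran the same way, where 8836 would be called in both if the lists were independent. The first principal component of the mouse values held 68.8% of the variance and placed DEHP mouse 4 at 53.2 and vehicle mouse 1 at 38.8, against -25.3, -36.2 and -30.4 for DEHP mouse 1 and vehicle mice 2 and 4. The difference between DEHP mice 4 and 1, estimated 6 times over vehicle partners, dyes and 3 slides, repeated with pairwise r across genes of 0.904 to 0.975.

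**Figure D3:**
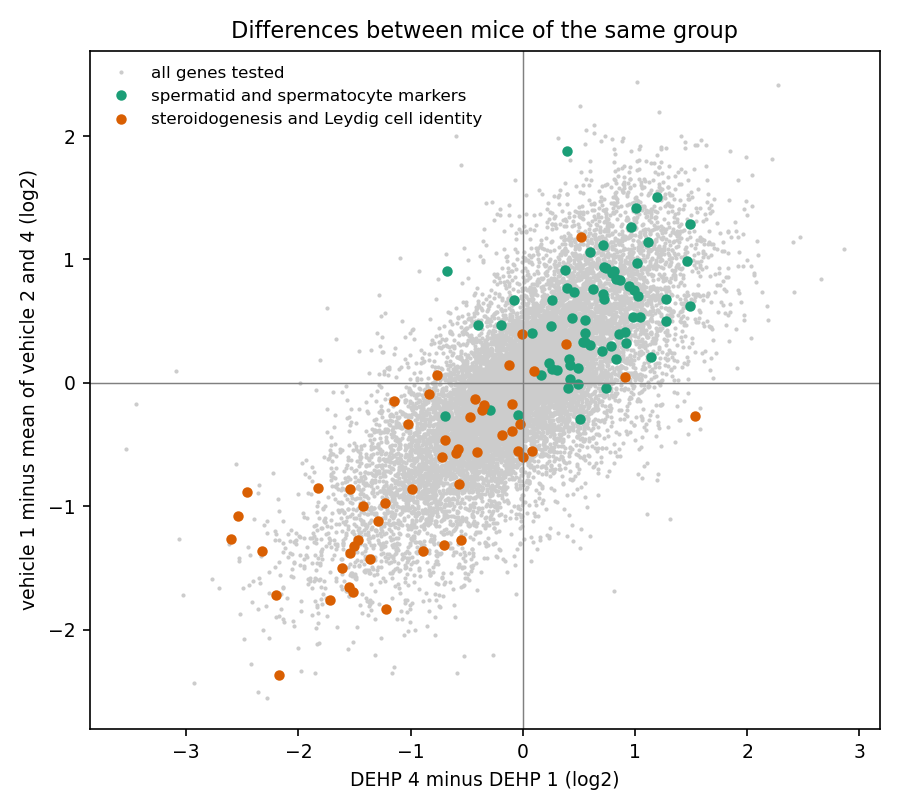
Each gene's difference between DEHP mice 4 and 1 (x axis, log2) against its difference between vehicle mouse 1 and the mean of vehicle mice 2 and 4 (y axis, log2), with all 15830 genes in grey, spermatid and spermatocyte markers in green and steroidogenesis and Leydig cell identity genes in orange. The green points lie mostly at upper right and the orange points mostly at lower left (r = 0.73 across all genes).

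A dye effect, which the swapped orientations remove from the group comparison, passed the threshold in limma for 7223 genes (45.6%), with a median size of 0.07 on the log2 scale over all genes.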

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

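With 21 groups of 6 arrays examined for a value far from the rest, 2 stood out, where chance marks about 1 in 20. The array of DEHP mouse 1 in Cy5 and vehicle mouse 4 in Cy3 had a median green signal of 131 scanner units, against 71.7 to 80.1 on the other 5 arrays of that orientation. Its log ratios correlated with those of its dye swap at r = 0.61, the lowest of the 6 pairs. Leaving it out, a choice made after seeing the data, kept the count of changed genes at 0 and of lists past the threshold at 6. The array of DEHP mouse 4 in Cy5 and vehicle mouse 1 in Cy3 had 1 saturated probe spot, against 0 on the other 5.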

How the results depend on the processing

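The count of genes changed by DEHP stayed at 0 under every alternative except 3. It was 2123 (1111 higher, 1012 lower) with 12 arrays as if independent, 104 (70 higher, 34 lower) with the pair of mice as a random block on 12 arrays, and 6 (6 higher) with DEHP mouse 4 and vehicle mouse 1 left out together, an alternative chosen after seeing the data that sets 1 DEHP mouse against 2 vehicle mice. The first 2 count each mouse several times. With 12 arrays as independent, 4 of the 10 splits of the 5 mice into 2 and 3 called as many genes as DEHP against vehicle, up to 9103, so repeated use of the same mice may account for these calls. In the fit on 5 mice the real count is 0, which all 10 splits reach whatever the data, so their number decides nothing. The highest other count was 3814, for DEHP mouse 4 and vehicle mouse 1 against the rest, which points to a structure of the mice that crosses the groups.

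The number of lists past the threshold, 6, was 3 with the scanner's processed signals, 3 with median centring, 0 with an estimated correlation and 0 with fry. It was 3, 3 and 16 on slides 1, 2 and 3 alone, chosen after seeing the data. Leaving out each mouse in turn gave 3 to 18 lists, 0 changed genes in each case (0 higher, 0 lower) and 924 to 5172 genes with a dye effect. Higher and lower lists numbered 3 and 0 without vehicle mouse 4, 1 and 17 without vehicle mouse 1, 2 and 13 without DEHP mouse 1, and 11 and 4 without DEHP mouse 4. A fit without a DEHP mouse holds 1 DEHP mouse, assumed to vary like the vehicle mice. None of these fits called a list with an estimated correlation (smallest adjusted p 0.708). Genes with a dye effect, 7223, were 14265 with median centring, 4485 after scaling to 1 spread, 11761 with no filter, 3615 in the authors' value table and 93 with the 2 mice left out together. Aquantile left the log ratios as they were.

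Without DEHP mouse 4, oxidative phosphorylation (adjusted p 0.01189) and ribosomal proteins (0.005609) turned upward, myoid markers turned and lost their call (0.6826), and spermatocyte markers (4.828e-05) were called lower. Lists called higher there but not with all 5 mice were steroidogenesis (0.0001991), PPAR alpha targets and oxidative stress (0.001234 each), xenobiotic metabolism (0.001644), cholesterol synthesis (0.02078), interferon and macrophage (4.828e-05), endothelial (0.02226) and stromal markers (0.01025). Without DEHP mouse 1, steroidogenesis (0.003856), PPAR alpha targets (0.006214), xenobiotic metabolism (0.02002), interferon (0.01323), macrophage (0.01386) and stromal markers (0.01894) were called lower instead, and spermatocyte markers (0.01042) higher. Over the 5 fits without a mouse, adjusted p ran from 0.0001991 to 0.8229 for steroidogenesis, 0.001234 to 0.8229 for PPAR alpha targets, 0.001644 to 0.8478 for xenobiotic metabolism, 0.02078 to 0.8306 for cholesterol synthesis, 4.828e-05 to 0.818 for interferon, 4.828e-05 to 0.8229 for macrophage, 0.003655 to 0.8478 for endothelial, 0.01025 to 0.8692 for stromal, 4.828e-05 to 0.669 for spermatocyte and 0.0002262 to 0.6826 for myoid markers. It ran from 0.01835 to 0.6737 for immediate early genes, 0.008404 to 0.6093 for inflammation, 0.001108 to 0.5176 for matrix, 0.0002334 to 0.79 for spermatogonial markers, 0.03665 to 0.871 for lipogenesis, 0.03633 to 0.9858 for cell cycle, 0.003554 to 0.5985 for p53 and apoptosis, 0.0009067 to 0.1181 for Sertoli cell markers and 0.001234 to 0.5502 for oxidative stress. It ran from 2.03e-06 to 0.8951 for oxidative phosphorylation and from 2.03e-06 to 0.9438 for ribosomal proteins. With the 2 mice left out together, oxidative phosphorylation (0.674) and ribosomal proteins (0.4697) turned. On slide 1 alone ribosomal proteins (0.9146) turned, and on slide 2 alone macrophage markers (0.02606) and oxidative phosphorylation (0.9749). The cause was not tested. Star ran from -0.69 to 0.84 over the alternatives.

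Mice share the numbers 1 and 4 between groups, but nothing says that a number pairs them. Deviations of same-numbered mice from their group means correlated across genes at -0.73 and -0.56. With the mouse number as a replicate block, 0 genes were changed (0 higher, 0 lower) and 5 lists passed.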

Other observations

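The tests of where DEHP mouse 4 and vehicle mouse 1 stand, the test of spermatid minus spermatocyte markers and the fit without 2 mice were chosen after the patterns were seen.

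The same-group differences reached well beyond germ cell and Leydig cell genes. In DEHP mouse 4 against DEHP mouse 1, macrophage, endothelial, stromal and myoid markers were lower in 21 of 29, 20 of 22, 15 of 16 and 14 of 15 genes. In vehicle mouse 1 against vehicle mice 2 and 4 they were lower in 21, 20, 13 and 11. Sertoli cell markers had medians near 0 in both differences, at -0.01 and -0.04.

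DEHP mouse 4 and vehicle mouse 1 stood apart from the other 3 mice. With the labels as given, this pattern crosses the groups, so by its own makeup it argues against the DEHP treatment alone. The first principal component restates the pattern and is no separate test. On it vehicle mouse 1 lay beside DEHP mouse 4, and DEHP mouse 1 lay between vehicle mice 1 and 4. The group difference on it was 0.296 of the difference between the DEHP mice. A differing amount of RNA from germ cells in the captured tissue is a candidate explanation: the 81 measured germ cell markers had median differences of 0.56 between the DEHP mice and 0.46 (0.459) between the vehicle mice, against -0.05 and -0.03 for other genes, and 65 of them were higher in both. By list, these medians were 0.72 and 0.72 for spermatids, 0.49 and 0.31 for spermatocytes, and 0.35 and only 0.09 for spermatogonia. The testis surrounds each Leydig cell cluster with tubules of germ cells, so that germ cell RNA is abundant next to the captured cells. Markers of the Sertoli cells, which also lie in the tubules, did not follow (-0.01 and -0.04), so the tubule markers did not move together. Swapped labels of DEHP mouse 1 and vehicle mouse 1 stay open as well: DEHP mouse 1 differed from vehicle mice 2 and 4 with an SD across genes 0.444 of that of vehicle mouse 1, and a difference in tissue makeup would give the same order. Under that swap DEHP mouse 4 and vehicle mouse 1 would be the treated mice, and the treatment would stay open as the source.

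Spermatid markers were called higher in the DEHP mice as a set and spermatocyte markers were not, at the preset correlation. The spermatid call had an adjusted p of 0.968 with an estimated correlation and 0.301 without DEHP mouse 4, and vehicle mouse 1 (0.26) lay above DEHP mouse 1 (-0.04). The call was lost in 3 alternatives and held in the others, always with the markers higher, but all reuse the same mice. Without DEHP mouse 4 and vehicle mouse 1 together, a fit of 1 DEHP mouse, the median difference was 0.24. A larger share of germ-cell RNA alone is a candidate explanation that these mice cannot decide. With the spermatocyte-marker median as a covariate, chosen after seeing the data, the median difference was 0.31. That fit had a camera adjusted p of 5.79e-11 at the preset correlation and 0.877 with an estimated correlation. The spermatid minus spermatocyte median was 0.21 and 0.35 in DEHP mice 1 and 4 and 0.05, -0.37 and -0.19 in vehicle mice 1, 2 and 4. An exact two-sided permutation test gave p = 0.2, where 0.1 is the smallest that 5 mice allow. Of the 10 splits of the mice, 2 gave as small a camera p, the real split included. The real split had 3.03e-11 with the markers higher, and vehicle mice 2 and 4 against the rest 1.26e-13 with the markers lower. Among the other splits with the markers higher, the smallest camera p was 1.91e-10, for DEHP mouse 4 and vehicle mouse 1. A share under 0.05 is out of reach with 10 splits.

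With DEHP mouse 4 and vehicle mouse 1 left out, 6 genes passed in limma: Slpi, Msln, Myl7, Rspo1, Krt7 and Tcp11, named here after their values were seen. That fit sets DEHP mouse 1 alone against 2 vehicle mice, which give all the spread, so it describes 1 extract and tests no effect of DEHP. Slpi was at 2.92 in DEHP mouse 1 and between -1.13 and -0.46 in the other 4 mice, and Msln at 2.85 against -0.88 to -0.51. Msln and Krt7 are known in mesothelium and simple epithelium. Cells of the mesothelium or epithelium captured with the Leydig cells of DEHP mouse 1 might be the source. Of 12 other markers, 8 were measured, with a median of 0.331 above the mean of the other mice and 1 highest in that mouse, short of the 0.5 set beforehand, so the question stays open.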
